A study of Homo sapiens with 2 samples.

How the data were processed

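Expression was measured on 1-colour Agilent arrays, with 1 array of OVCAR-3 control cells and 1 array of cells labelled iOVCAR-3. Per the labels' protocols, total RNA was extracted with Trizol, and Cy3-labelled cRNA was made from 0.5 ug of RNA with a linear amplification kit. The culture protocol in the labels, with 20% serum replacement and 10 ng/mL bFGF, names iOVCAR-3 cells, and the medium of the control cells is not stated. The deposited files hold scanner intensity values per spot. Per the file headers, the intensity was background-corrected by Agilent Feature Extraction with spatial and multiplicative detrending, and surrogate values replaced signals too close to background. The headers give version 10.5.1.1 of that software and the submitters' processing notes version 9.1, and which one applied was not settled. Both arrays were on the same slide and in the same scan per the file headers, so slide and scan do not separate the groups. The error and background columns and the probe annotation came with the same files as deposited.

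Each array holds 62976 spots, of which 60901 carry 58201 noncontrol probes. Of these probes, 300 are spotted 10 times. Control spots were left out, as were 169 outlier-flagged spots on the OVCAR-3 array and 64 on the array labelled iOVCAR-3. The processed intensity was converted to log2, spots of 1 probe were averaged, and the array's 75th percentile was subtracted. A probe counted as detected where most of its spots carried the flag for well above background. Each gene was represented by its probe with the highest mean signal over both arrays. Where a single array was above background, the difference is given as a bound, the bright array's value against the higher of the dim probe's own signal and the lowest signal well above background on the dim array. A gene counts as below background only if all its probes are.

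Probe names were updated through RefSeq accessions, symbols and unique synonyms of a GRCh38 gene table, used for names alone. This named 35015 of 58201 probes and changed 3923 names, and the array's own name was kept otherwise. The 179 probes on the Y chromosome or at XIST were left out. This also removed CD24 from the stem cell marker list, since its probe is placed on the Y chromosome. Probe positions are those of the array annotation, in hg19. The files do not say which exon or untranslated region a probe lies in. The POU5F1 and KLF4 coding probes were recognised by translating the probe sequence and finding the protein's known POU domain or zinc finger stretch. None of the other factor probes was recognised as coding in this way, which does not search the full proteins. Every frame of the MYC probes holds a stop codon.

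With 1 array per group there are no residual degrees of freedom, so no test was run and no p-value is given. Genes were counted at 2-fold, and the spread of repeated spots was the only error. The 32 gene lists hold 493 distinct genes and were fixed before the data were examined. Each list is described by the counts of members at least 2-fold higher or lower, its median log2 difference over members above background on at least 1 array, and the percentile of that median among 10000 random lists of protein-coding genes matched on mean signal in 20 bins. Named genes followed a rule fixed at the same time. It takes the 4 reprogramming factors, the 10 largest differences each way among genes detected on both arrays with an approved-style symbol and probes of the same sign, and the 5 largest bounds each way. It also takes up to 4 members per list with the largest differences, and any member of the pluripotency and other-cell-type lists.

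The steps were tested on simulated data, with the OVCAR-3 array copied, spot noise added and 200 of 43243 genes changed. All 50 genes made 3-fold higher and all 50 made 8-fold higher were called, as were 46 of 50 made 3-fold lower and 47 of 50 made 8-fold lower. None of 34473 unchanged genes above background was called, a count of 0. The noise was normal, with an SD of a log2 difference of 0.142, or 0.223 for dim probes. A 2-fold call of an unchanged gene was therefore hardly possible. A list of 20 genes raised 8-fold lay at percentile 100, and 56 of 1000 lists of unchanged genes lay outside the central 95% of random lists. The simulated data held no variation of labelling, hybridisation or culture and no shared regulation of genes. They give no false-call rate for the real arrays.

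The alternatives were quantile normalization, median centring, no scaling, cyclic loess, scaling on spike-in controls, normexp background correction with an offset of 50, the mean of all probes, a filter to genes above background on both arrays, no filter, keeping flagged spots, a 3-fold threshold, and a weaker detection flag. R 4.3.3 with limma 3.58.1 made the normalizations, and Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6 made the counts.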

Results

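Gene expression was measured in OVCAR-3, a cell line established from a human ovarian adenocarcinoma, and in iOVCAR-3, the same line after transduction with the Yamanaka factors OCT4 (POU5F1), SOX2, KLF4 and c-MYC by Sendai virus vectors. Sendai virus is an RNA virus whose vectors carry the coding sequences without entering the genome. The labels describe iOVCAR-3 as induced ovarian cancer initiating cells, and the design compares the 2 conditions. Total RNA of each was labelled with Cy3 and hybridised to a 1-colour Agilent array of 58201 probes, with 1 array per condition. There are no replicates, so no difference below has a test or a p-value, and each is a comparison of 2 arrays. The number of arrays limits the precision. The spread that could be measured is that between spots of 1 probe. Among 295 probes spotted 10 times per array, the SD of a log2 difference between single spots was 0.142. It was 0.223 in the 98 dimmest of these probes and 0.0716 in the 98 brightest. The 75th percentile of the processed signal was 410 on the OVCAR-3 array and 416 on the other, 78.5% and 76.4% of spots were well above background, and 0 spots were saturated.

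The transduced genes were examined first. None of POU5F1, SOX2, KLF4 and MYC was at least 2-fold higher on the array labelled iOVCAR-3, and POU5F1 was 3.66-fold lower. SOX2 was 1.87-fold lower, MYC 1.81-fold lower and KLF4 1.09-fold higher, all well above background on both arrays. The POU5F1 value comes from the brighter of its 2 probes (hg19 chromosome 6, 31132178 to 31132237), which was not recognised as coding. The probe of SOX2 (chromosome 3, 181431877 to 181431936) and both probes of MYC were not recognised as coding either. Probes outside the coding part see the cell's own transcript and not a vector that carries the coding sequence alone, so they check nothing about the labels. The other POU5F1 probe (chromosome 6, 31133025 to 31133368) reads the POU domain and was 1.95-fold lower, although related POU5F1 pseudogenes share much of this sequence. The KLF4 probe (chromosome 9, 110248049 to 110248108) reads the zinc fingers and gave the log2 difference of 0.12. The coding probe of POU5F1 goes against the label if the vectors were still expressed, and that of KLF4 showed no 2-fold rise. The sample is therefore called the array labelled iOVCAR-3 throughout, and every direction below rests on that label. With scaling on the spike-in controls KLF4 turned to a log2 difference of -0.22, and POU5F1, SOX2 and MYC were all at least 2-fold lower.

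Across the transcriptome, TGFBI, a secreted matrix protein induced by TGF-beta, was 589-fold higher on the array labelled iOVCAR-3 (probe at hg19 chromosome 5, 135399343 to 135399402). PLIN2, a coat protein of lipid droplets (chromosome 9, 19116370 to 19116429), was 312-fold higher at its brightest probe, with the lowest of its 3 probes at a log2 difference of 2.68. The matricellular protein gene CCN5 was 224-fold higher, the surface glycoprotein gene THY1 148-fold, and NNMT, which methylates nicotinamide, 137-fold. CA9, a carbonic anhydrase induced by hypoxia, was 87.0-fold higher, the protease inhibitor CST6 71.4-fold, CALCA 57.7-fold (lowest probe 4.21), S100A8 53.1-fold and the collagen gene COL1A2 51.2-fold. On the OVCAR-3 array, PLIN2, THY1 and COL1A2 had log2 signals of -3.899, -4.069 and -4.115. The lowest signal well above background there was -4.503, so the folds of these genes rest on a dim signal and are imprecise. In the other direction, the histone gene H4C3 (chromosome 6, 26104468 to 26104527) was 205-fold lower at its brighter probe, while its second probe had a log2 difference of -3.38. FST, which encodes the activin antagonist follistatin (chromosome 5, 52780837 to 52780896), was 179-fold lower, and the homeobox gene EMX2 106-fold lower. The tyrosine kinase SYK was 92.3-fold lower, FLG 62.2-fold (smallest probe difference -3.61), CILP 61.9-fold, PODXL 47.5-fold, CCDC146 46.4-fold, EBF3 44.5-fold and NPR3 42.4-fold.

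Other genes were well above background on a single array and have a bound in place of a fold. CYP4B1 was at least 267-fold lower on the array labelled iOVCAR-3, FMO2 at least 59.9-fold, the laminin gene LAMA1 at least 54.9-fold, SOSTDC1 at least 36.5-fold and CTSZ at least 28.7-fold. MACC1-AS1 was at least 34.5-fold higher, APCDD1L at least 27.7-fold, ABCB4 at least 23.8-fold, STMN2 at least 22.0-fold and CLEC7A at least 21.6-fold. These bounds set the bright array against the higher of the dim probe's own signal and the lowest signal that was well above background on the dim array.

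Of 43242 genes with a probe, 34703 were well above background on the OVCAR-3 array and 33793 on the array labelled iOVCAR-3. At least 2-fold differences, bounds included, comprised 1901 genes higher and 1947 genes lower on the array labelled iOVCAR-3. Of the protein-coding genes, 1373 were higher and 1162 lower. Among the 32918 genes measured above background on both arrays, 29626 (90.0%) lay within 2-fold, 213 were at least 8-fold higher and 147 at least 8-fold lower. For comparison, 119 of 24533 pairs of spots of 1 probe on 1 array (0.485%) were at least 2-fold apart. Such pairs hold spot-to-spot noise alone, not variation of labelling, hybridisation or culture, so this share is no error rate for the differences between arrays. Where at least 2 probes of a gene were above background on both arrays and the gene differed at least 2-fold, all its probes had the same sign in 660 of 791 genes (83.4%). The higher genes made up 49.4% of the calls, but 22.8% with spike-in scaling, which moved the median log2 difference of all genes from -0.05 to -0.40. The labels give a culture medium for iOVCAR-3 alone, with 20% serum replacement and 10 ng/mL bFGF, so medium and transduction were not separated.

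**Figure D1:**
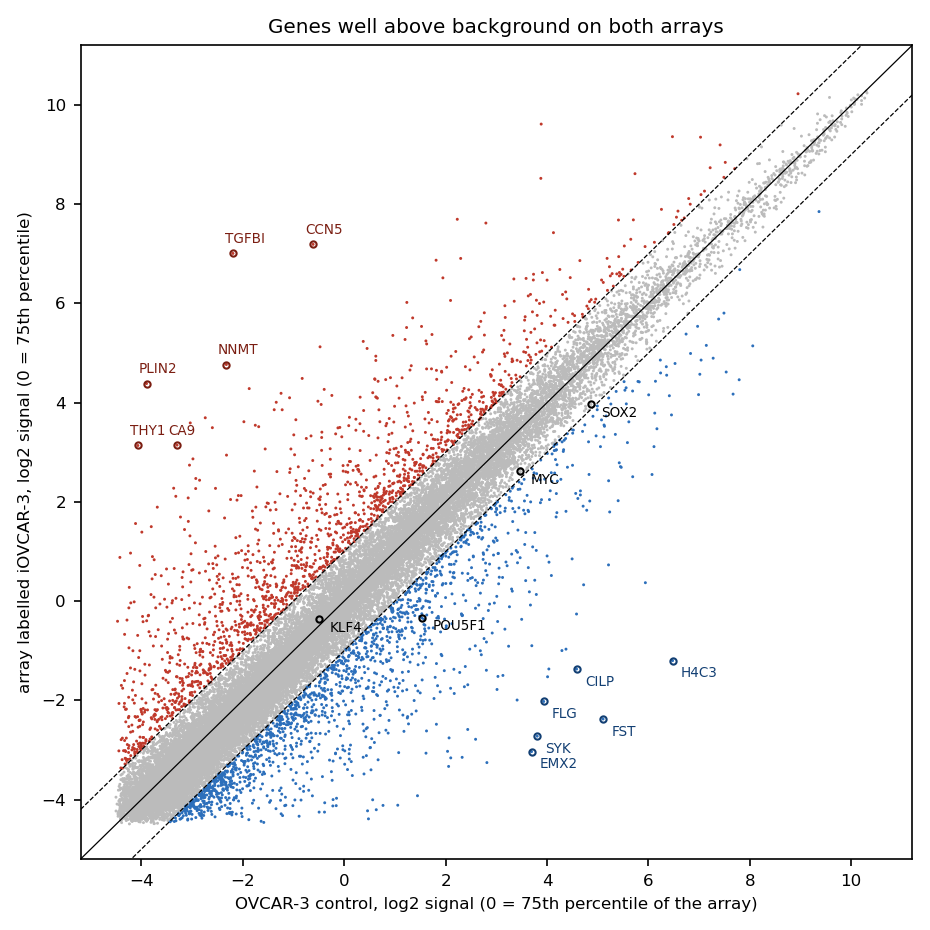
Each point is a gene well above background on both arrays, with its log2 signal on the OVCAR-3 array (x axis) and on the array labelled iOVCAR-3 (y axis), where 0 is the array's 75th percentile. The solid line marks equal signal and the dashed lines 2-fold differences. The 1669 red genes were at least 2-fold higher and the 1623 blue genes at least 2-fold lower. Among the named genes, TGFBI and H4C3 lie farthest from the line on their sides.

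The remaining comparisons used 32 gene lists fixed before the data were examined. Each list's median log2 difference was set beside 10000 random lists of the same size, matched on signal, as a description of these 2 arrays. Spike-in scaling shifted all log2 differences by -0.34, which turned the positive medians of the stem cell, endothelial, YAP, chaperone and drug efflux lists negative and left the direction of the other medians given here. Pluripotency genes went both ways. Of 24 genes, 16 were above background, of which 2 were at least 2-fold higher, 4 at least 2-fold lower and 10 neither. PODXL, a sialomucin of pluripotent and tumour cells, was 47.5-fold lower and the NODAL antagonist gene LEFTY1 15.6-fold. The transcription factor gene FOXD3 was 7.34-fold lower and the telomerase gene TERT 2.57-fold. On the array labelled iOVCAR-3, LEFTY1 and FOXD3 had log2 signals of -4.123 and -4.461. The lowest signal well above background there was -4.491, so the folds of LEFTY1 and FOXD3 rest on a dim signal and are imprecise. The methyltransferase gene DNMT3B was 4.22-fold higher. Its log2 difference was 0.76 when averaged with its second probe, which was below background on at least 1 array. LIN28B, which blocks let-7 processing, was 3.76-fold higher. NANOG was 1.82-fold lower, and LIN28A, DPPA4 and ZFP42 were not well above background on either array. The list median was -0.33, at percentile 3.14 of the random lists, or 1.92 with quantile normalization and 1.94 with cyclic loess. It was -0.0643 over all 24 genes with no filter on dim probes. With spike-in scaling 7 pluripotency genes were at least 2-fold lower. Among germ layer genes, SOX17 was 10.8-fold lower, and of 14 genes above background 1 was at least 2-fold higher and 4 at least 2-fold lower (median -0.35, percentile 3.76). With its 2 genes seen on a single array set at their bounds, the germ layer median was -0.27, and it was -0.17 with cyclic loess and -0.12 with normexp.

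Ovarian cancer stem cell markers went both ways, with 3 at least 2-fold higher, 3 at least 2-fold lower and 9 neither (median 0.04, percentile 62.9). The Wnt target gene LGR5 was at least 16.7-fold lower. The receptor tyrosine kinase gene KIT was 8.50-fold lower, with its smallest probe difference at -1.01. The aldehyde dehydrogenase gene ALDH1A3 was 6.73-fold higher at its brighter probe, with the other at 0.48, and the endoglin gene ENG was 3.53-fold higher.

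Mesenchymal genes were higher on the array labelled iOVCAR-3, with 14 of 20 at least 2-fold higher, 1 at least 2-fold lower and 5 neither. Their median log2 difference was 2.09, where 95% of matched random lists lay between -0.25 and 0.25. The actin-binding protein gene TAGLN was 98.9-fold higher at its brighter probe, although its second probe had a log2 difference of -0.46. Fibronectin (FN1) was 43.2-fold higher, smooth muscle actin (ACTA2) 21.4-fold, and the cadherin gene CDH11 16.1-fold, with a second CDH11 probe at -0.03. Of 22 epithelial genes, 2 were at least 2-fold higher, 3 at least 2-fold lower and 17 neither (median -0.03, percentile 19.6). This split depended on the scaling, with 2 higher and 5 lower under quantile normalization or cyclic loess. With spike-in scaling 1 was higher and 8 lower, and the epithelial median was -0.37. The transcription factor gene OVOL1 was 7.92-fold higher, the simple keratins KRT18 and KRT8 were 2.86-fold and 2.70-fold lower, and the junction gene OCLN was 2.83-fold lower. The probes of KRT8 disagreed, with log2 differences from -1.59 to 0.58. The squamous and basal list holds keratins and other genes, TP63 and IVL among them. Of its 13 genes above background, 8 were at least 2-fold higher, 1 at least 2-fold lower and 4 neither (median 1.70). KRT14 was 23.9-fold higher (second probe 1.75), its partner KRT5 23.4-fold, KRT17 15.7-fold and KRT4 12.1-fold.

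Fibroblast markers were higher in 6 of the 8 genes above background by at least 2-fold, with 2 neither. THY1 was 148-fold higher, COL1A2 51.2-fold, the proteoglycan gene DCN 37.7-fold and the fibrillin gene FBN1 at least 5.31-fold. As given above, the folds of THY1 and COL1A2 rest on a dim OVCAR-3 signal and are imprecise. The median was 4.07, or 3.07 with FBN1 at its bound, 2.21 with normexp background correction, and 1.60 over all 12 genes with no filter on dim probes. The fibroblast genes COL3A1, LUM, POSTN and COL6A3 were not well above background on either array. Hematopoietic markers did not shift as a group, with 1 of 9 at least 2-fold higher and 1 at least 2-fold lower (median -0.19, percentile 25.8). HLA-DRA, a class II antigen presentation gene, was at least 23.5-fold lower and CD14 2.03-fold higher. With quantile normalization, spike-in scaling or normexp, 0 hematopoietic markers were at least 2-fold higher. Of 8 endothelial markers, 1 was at least 2-fold higher and 2 at least 2-fold lower (median 0.24, percentile 90.0, and 0.0722 with probes averaged). The angiopoietin receptor gene TEK was at least 6.88-fold lower.

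Genes of the ovarian and Mullerian lineage were lower on the array labelled iOVCAR-3, with 8 of 18 at least 2-fold lower, 2 at least 2-fold higher and 8 neither. Their median was -0.69, where 95% of random lists lay between -0.21 and 0.30. EMX2 was 106-fold lower, the endoderm and Mullerian factor SOX17 10.8-fold and the Wilms tumour gene WT1 10.4-fold, while the osteopontin gene SPP1 was 17.4-fold higher. Notch pathway genes had the lowest median of the 32 lists, -1.32, with 7 of 12 at least 2-fold lower and 0 higher. The Notch target genes HEY2, NRARP and HEYL were 29.2-fold, 17.4-fold and 9.61-fold lower, and the ligand gene JAG1 8.66-fold lower. Wnt targets were at least 2-fold lower in 4 of 12 genes and higher in 2 (median -0.53, percentile 0.36, and -0.31 with normexp). LGR5 was at least 16.7-fold lower, APCDD1 13.2-fold and LEF1 3.96-fold lower, while TCF7 was 7.34-fold higher (second probe 1.63). Genes of the FGF and ERK response were at least 2-fold higher in 7 of 14 and lower in 1 (median 1.05, or 0.65 with normexp background correction). PHLDA1 was 13.6-fold higher at 1 of its 2 probes, with the other at -0.28, the phosphatase gene DUSP5 was 12.3-fold, the immediate-early gene FOS 4.45-fold and IER3 4.33-fold higher. YAP targets were mixed, with 2 of 11 higher and 2 lower (percentile 91.4), including F3, the tissue factor gene, 11.6-fold higher and TGFB2 4.39-fold lower.

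**Figure D2:**
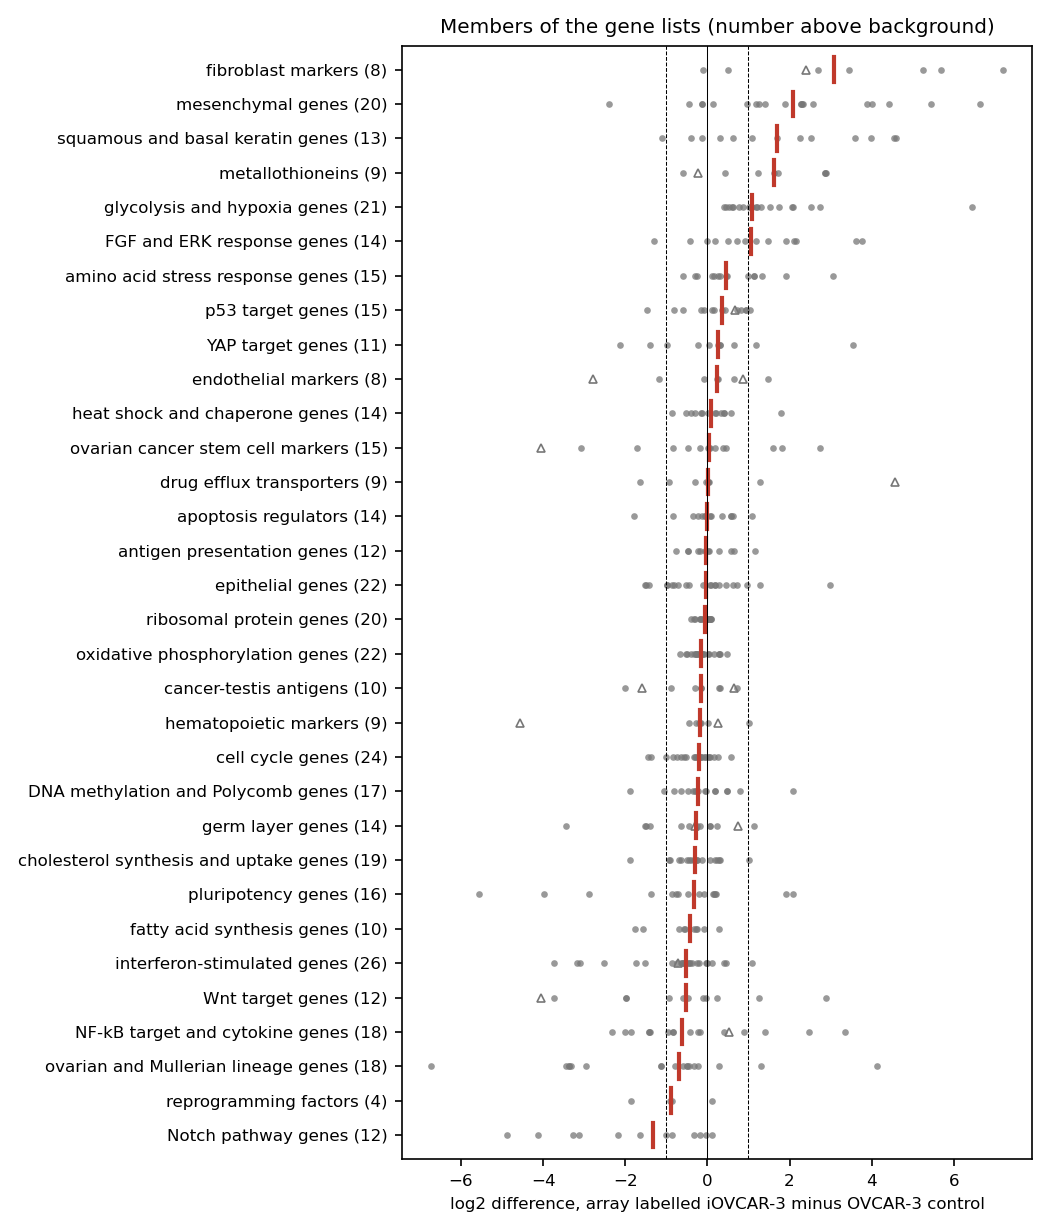
Log2 differences of list members, array labelled iOVCAR-3 minus OVCAR-3 control (x axis), for the 32 gene lists (rows, with the number of members above background). Grey points are genes above background on both arrays, open triangles are bounds for genes above background on a single array, and red bars are list medians with bounds. Dashed lines mark 2-fold differences. The fibroblast list lies highest, with a median of 3.07, and the Notch list lowest, at -1.32.

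All 21 glycolysis and hypoxia genes had a positive difference, and 14 were at least 2-fold higher on the array labelled iOVCAR-3. All 21 stayed positive under every scaling, but the number at least 2-fold higher was 10 with quantile normalization and 7 with spike-in scaling. Their median was 1.08, where 95% of random lists lay between -0.16 and 0.30. CA9 was 87.0-fold higher, the glycolytic regulator gene PFKFB4 6.69-fold, the enolase gene ENO2 5.75-fold and the lactate exporter gene SLC16A3 4.27-fold. None of 22 oxidative phosphorylation genes differed 2-fold (median -0.15, percentile 0.66, and -0.28 with quantile normalization), and the largest difference was at ATP5PO, 1.59-fold lower. With spike-in scaling 1 of the 22 was at least 2-fold lower. Metallothioneins, which bind zinc and copper, were at least 2-fold higher in 6 of 9 genes and lower in 0 (median 1.63). MT2A was 7.36-fold higher, MT1E 7.34-fold and MT1B 7.23-fold, but MT1E had a second probe at -0.18, and these genes are near-identical in sequence. Genes of the amino acid stress response were at least 2-fold higher in 5 of 15 and lower in 0 (median 0.46, percentile 99.4), among them the mTOR inhibitor gene DDIT4, 8.27-fold higher, and CTH, 3.77-fold higher. With spike-in scaling 2 of the 15 were at least 2-fold higher, 8 were above 0 and the median was 0.11. Fatty acid synthesis genes had a median of -0.43 (percentile 0.44), with the elongase gene ELOVL6 3.37-fold lower and the desaturase gene FADS2 2.97-fold lower. In the cholesterol list 17 of 19 genes lay within 2-fold (median -0.30, percentile 0.32), with HMGCS1 3.70-fold lower. The number at least 2-fold lower was 1, or 4 with spike-in scaling.

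Interferon-stimulated genes were at least 2-fold lower in 6 of 26 and higher in 1 (median -0.52, percentile 0.01). The restriction factor gene BST2 was 13.3-fold lower, MX1 8.63-fold and IFI44L 5.72-fold. NF-kB targets and cytokines were at least 2-fold lower in 6 of 18 and higher in 3 (median -0.63, or -0.39 with normexp). The chemokine genes CCL2 and CXCL3 were 5.03-fold and 4.03-fold lower, while IL6 was 10.2-fold and LIF 5.59-fold higher, each with a second probe at a smaller difference of 0.23 and 0.66. Cell cycle genes lay within 2-fold in 21 of 24 cases, with 3 at least 2-fold lower (median -0.21, percentile 0.83). The number lower was 5 with spike-in scaling and 2 with median centring or no scaling. The replication genes MCM3, TYMS and MCM2 were 2.70-fold, 2.58-fold and 2.00-fold lower, and TOP2A was 1.79-fold lower. Among p53 targets, 13 of 15 lay within 2-fold (median 0.36, percentile 98.3, and 0.18 with normexp), with BTG2 2.79-fold lower and GADD45A 2.05-fold higher. Median centring gave 3 higher in place of 1 and averaged probes 2. Quantile normalization, cyclic loess, spike-in scaling and normexp gave 0 p53 targets at least 2-fold higher. Of 9 drug efflux transporters, ABCB4 was at least 23.8-fold higher, ABCC3 2.42-fold higher and ABCA1 3.14-fold lower, with a second ABCA1 probe at -0.39 (list percentile 62.5). All 20 ribosomal protein genes lay within 2-fold, with a median of -0.05 that was 0.06 with median centring of the arrays.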

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

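All tests of explanations in this part were chosen after the results they bear on were seen. Control probes outside the comparison carried signal. The E1A spike-in probes, RNAs added in fixed amounts with the labelling kit, were brighter on the array labelled iOVCAR-3 by a median of 0.37 on the log2 scale over the 8 of 10 probes well above background. The difference was positive in 7 of the 8, from 0.34 to 0.39, and -0.02 in the dimmest. Of 96 ERCC control probes, for which no added RNA is stated, 2 were well above background on both arrays, with log2 differences of -0.09 and -0.02.

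The first pattern weighed is that POU5F1, SOX2, KLF4 and MYC were not higher on the array labelled iOVCAR-3. Probes that miss the vectors' coding sequence do not account for POU5F1 and KLF4, since the larger difference of their coding probes was 0.12. For SOX2 and MYC this could account for the lack of a rise, since none of their 3 probes was found to read coding sequence. It stays open, as such probes cannot show whether the vectors were expressed. Swapped labels stay open too. A swap with active vectors would put both coding probes lower on the array labelled iOVCAR-3. The POU5F1 coding probe was 1.95-fold lower there, while the KLF4 difference was 0.12, or -0.22 with spike-in scaling. A swap after loss of the vectors forbids no value. Loss or silencing of the vectors during culture is a biological explanation that was not tested.

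The second pattern is the higher signal of all 21 glycolysis and hypoxia genes. Scaling does not account for it, since the lowest list median relative to all coding genes was 1.00 over the main scaling, quantile normalization and cyclic loess, above the central 95% of random lists in each. The other scalings shift all genes alike and cannot set a list apart. Culture medium, density or oxygen may underlie it and cannot be told apart from the transduction, because the labels give a medium for 1 group alone and each group has 1 culture. An effect of the transduced factors remains open and untested.

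The third pattern is the higher signal of mesenchymal genes and fibroblast markers. Human fibroblasts mixed into the culture would bring all their abundant transcripts. On the array labelled iOVCAR-3, 8 of the 12 fibroblast genes were well above background, THY1 and COL1A2 among them, and 6 of the 8 were at least 2-fold higher. COL3A1, LUM, POSTN and COL6A3 were not well above background, which goes against fibroblasts that express the whole list. An admixture of fibroblasts without these transcripts stays open. Scaling does not account for the pattern, with a lowest relative mesenchymal median of 2.09, tested in the same way. Of the 12 fibroblast genes, none is on the mesenchymal list, and 7 were above background on the OVCAR-3 array too. A state of the transduced cells, the medium, or a sample of other cells under this label remain open and were not tested.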

How the results depend on the processing

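The limits of these results are the single array per group, the low signal of dim genes, and the scaling. List medians in this part are taken relative to all protein-coding genes, unlike those of the report, so median centring, no scaling and spike-in scaling, which shift all genes alike, cannot move them. Of the 224 list medians under the other alternatives, 24 moved by more than 0.142, the SD between single spots, which is not an error of a median. Of the 119 named genes with at least a 2-fold difference, none changed sign in 1175 values, and 101 kept 2-fold under every alternative that gave a value. Many of these values could not change sign. Median centring, no scaling and spike-in scaling shift all genes by 0.11, 0.02 and -0.34, and the filters keep the measured sign. KLF4, within 2-fold, changed sign with spike-in scaling. Counts of detected genes stayed within 1.5 times (up to 39859 and 39413 with the weaker flag). No paired analysis was possible because each group has 1 array. Except where said, the cause of a shift was not tested. Spike-in scaling gave 1204 genes higher and 4074 lower, since it moves all genes by one amount, to a median of -0.40 from -0.05, and 22.8% of calls were higher against 49.4%. Median centring moved that median to 0.06 and the share to 58.8%. The count lower was 985 with normexp and 3226 with no filter, which adds dim genes. At 3-fold, 910 were higher and 794 lower.

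With spike-in scaling the differences were -2.21 for POU5F1, -1.25 for SOX2, -0.22 for KLF4 and -1.20 for MYC. POU5F1 was -1.68 with normexp and -1.42 with its probes averaged. With normexp, list medians relative to all coding genes were 1.59 for mesenchymal genes (2.09 in the main setting) and 0.18 for p53 targets (0.36). They were -0.38 for NF-kB targets (-0.62), -0.31 for Wnt targets (-0.52), -1.17 for Notch (-1.32) and 0.65 for FGF and ERK response (1.06). Normexp gave -0.11 for germ layer genes (-0.34), 1.48 for the squamous and basal list (1.71) and 2.21 for fibroblast markers (4.07). Averaged probes gave 1.75 for mesenchymal genes, -0.35 for interferon-stimulated genes (-0.51) and 0.15 for antigen presentation (-0.02). They gave 1.25 for metallothioneins (1.64), 1.21 for the squamous and basal list and 0.0936 for endothelial markers (0.25). No filter gave -0.0635 for pluripotency genes (-0.32), 1.90 for mesenchymal genes and 1.43 for metallothioneins. This setting gave 1.39 for the squamous and basal list and 1.60 for fibroblast markers. With genes above background on both arrays, NF-kB targets were at -0.83 and fibroblast markers at 3.45, which drops FBN1. Germ layer genes were at -0.19 with quantile normalization and -0.18 with cyclic loess.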

Other observations

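Lists not described above showed smaller or mixed differences. Of 17 DNA methylation and Polycomb genes, 14 lay within 2-fold (median -0.22, or -0.0842 with normexp, percentile 4.77). DNMT3B was 4.22-fold higher on the array labelled iOVCAR-3, while the Polycomb gene CBX2 was 3.69-fold lower at 1 of its 2 probes, with the other at 0.42, and the demethylase gene TET1 2.08-fold lower. With probes averaged, 0 of the 17 were at least 2-fold higher and 0 at least 2-fold lower, DNMT3B included, at 0.76. The DNMT3B average takes in a probe below background on at least 1 array. Of 14 apoptosis regulators, 12 lay within 2-fold (percentile 40.9), with the BIM gene BCL2L11 3.48-fold lower at its brightest probe, with another at 0.04, and BID 2.12-fold higher. With quantile normalization or spike-in scaling, 0 of the 14 were at least 2-fold higher. Antigen presentation genes lay within 2-fold in 11 of 12 (percentile 28.9), with HLA-F 2.25-fold higher at its brighter probe and the other at 3.38. Heat shock and chaperone genes lay within 2-fold in 13 of 14 (percentile 60.7), with the small heat shock protein gene HSPB1 3.44-fold higher and its lowest probe at 0.03. Among 10 cancer-testis antigens above background, SSX1 was 4.03-fold lower and XAGE1A at least 3.01-fold lower, and 8 lay within 2-fold (percentile 38.4).

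A hypothesis formed on these data, with its test chosen after the values were seen, was that genes of 1 chromosome region differed together. The 31670 genes with a position were placed in 517 windows of 5 Mb with at least 20 genes. The SD of the window medians was 0.0986, above the highest of 1000 shuffles of the differences (0.0804). Chance placement of independent genes therefore does not account for the spread over all windows. The shuffles treat neighbouring genes as independent, and no single window was tested, so the hypothesis for 1 region stays undecided. The lowest median was -0.52 on chromosome 3 (hg19 105000001 to 110000000, 29 genes, 10 at least 2-fold lower and 0 higher). The next lowest, -0.34, was in the adjoining window (110000001 to 115000000, 53 genes, 8 lower and 0 higher). The highest median was 0.24 on chromosome 17 (5000001 to 10000000, 147 genes, 20 higher and 2 lower). In the windows beside that one the medians were 0.05 and -0.10. Clusters of related or overlapping genes, shared regulation of neighbours and a difference in copy number between the cultures may each give such a pattern, and these arrays hold no DNA measurement to separate them.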
